A study of Homo sapiens with 96 samples.

How the data were processed

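Human NK cells and innate lymphoid cells from jejunum, spleen and lung were made into Smart-seq2 libraries, per the labels' protocols. Tissue was digested to free the cells before sorting, per the labels' protocols. Reads were called with CASAVA 1.8.2 and aligned with STAR 2.3.0 to hg19, per the submitters' processing notes. The deposited table holds counts of reads per gene symbol, whole numbers without molecular identifiers. The program that counted the reads, the gene annotation, the strandedness of the libraries and the sort gates are not given in the sources used here. Reads of overlapping genes, and of close copies such as KIR, KLRC, HLA, HSPA1A and HSPA1B, cannot be told apart from the table. The labels list 96 samples and the table has columns for 92, and the 4 samples without a column were not analysed here.

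The table has 23658 gene symbols, of which 21229 were found in the reference annotation used for names. The 123 sex-linked genes (annotated on Y and not on X, with the gene of X inactivation) were left out before any step, which left 23535. Library totals ranged from 169417 to 1630063 counts (median 684141). No pair of libraries was identical. Between repeat libraries of a donor and group, the chi-square per degree of freedom over genes with a summed count of at least 20 was 2.31 to 30.0 (median 7.28, 86 pairs, where counting error alone gives 1), so repeat libraries differed by more than counting error. Repeat libraries were summed per donor, tissue and cell type into 33 sums (595449 to 4291274 counts, median 1989498). At the median total 1 CPM is about 2 counts, so levels under 5 CPM rest on about 10 counts or fewer. The MTRNR2L genes, 9 nuclear copies of mitochondrial ribosomal RNA, took 3.8 to 39.9% of a sum and stayed in the library sizes.

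The sums of 8 groups (31 sums) were fitted together with edgeR 4.0.16 in R 4.3.3: filterByExpr with a minimum count of 10 (14792 genes kept), TMM factors, and the quasi-likelihood F test with robust dispersion (common biological coefficient of variation 0.685, median prior degrees of freedom 9.08). Lung ILC3 and lung NK, from 1 donor each, were left out of the fit. There were 12 comparisons of groups and 3 interactions (the jejunum over spleen change of a cell type against that of another). Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes, and within each list the p-values were also adjusted over the list alone. Single tests measured the spread between donors. Log2 fold changes are edgeR estimates with their standard errors, levels are CPM with the SD over donors, and fold is 2 to the size of the log2 fold change. Single-gene CPM used the total of the genes kept by the filter times its TMM factor (computed over all 33 sums). Summed CPM of marker lists, and single genes that the filter left out, used the plain total of all genes. A single gene can therefore exceed the sum of the list that holds it. For a gene without a read in a group the fold is a lower bound with the group's pooled count set at 3, and with 1 to 3 pooled reads a ratio of pooled counts is given with a 95% interval. Bounds and intervals cover counting error only, since amplified copies cannot be told apart.

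There were 28 gene lists, fixed before the data were examined, each with at least 3 tested members: cytotoxic effector, NK receptors, KIR, type 1, type 2, type 3, helper ILC shared, tissue residency, recirculation, gut homing, TGF-beta response, immediate early, heat shock, NF-kB response, interferon stimulated, proliferation, glycolysis, oxidative phosphorylation, ribosomal proteins, and markers of T cells, B and plasma cells, myeloid cells, mast cells, intestinal epithelium, lung epithelium, stroma and endothelium, erythroid cells and plasmacytoid dendritic cells. They were tested with camera (limma 3.58.1) on voom values of the same fit at a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data. Adjustment was over all lists and comparisons for each setting. A list of mitochondrially encoded genes had no member in the table.

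Genes were named by a rule fixed in advance: per comparison the 12 higher and 12 lower genes with the smallest p among those called whose donors all lay on the side of the change from the other group's mean (6 and 6 where a group had 2 donors and for interactions), plus members of the lists and a set of key markers. The condition on donors was not applied to interactions. Sex-linked genes, genes without an official symbol, segments of antibody and T cell receptors, HLA genes and KIR outside the list were not named, and single values of some list members are not reported here.

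The same number in titles marks the same donor across tissues and cell types, per the labels. Sums of the same donor deviated together from their group means within a tissue (correlations of 0.115 to 0.456, against medians of -0.13 to -0.064 for other donors) and less so across tissues (medians of -0.051 to 0.152). The planned fit had no donor term, and a fit with the donor as a block was the alternative: it called 48 genes in spleen ILC1 against NK, where 8 were called without it. Other alternatives set in advance were DESeq2 1.42.0 (Wald test), RLE size factors in edgeR, no filter on low counts, limma-trend on mean log2 CPM of libraries with equal weights, leaving out each of the 5 donors in turn, and leaving out libraries with few reads (under 68414.1 counts, 0.1 of the median total, which no library was). After the data were seen, fits without 2 jejunum sums that stood apart were added (an ILC1 sum with myeloid RNA and little IL7R, and an ILC3 sum with high MTRNR2L and epithelial RNA), and fits without 3 jejunum NK sums with IGJ above 10000 CPM.

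The gene and list tests were tested on simulated data drawn from the real means and library sizes with 200 changed genes. In spleen ILC3 against NK (14140 genes) edgeR recovered 8, 44, 82 and 88% of genes changed 2, 4, 8 and 16-fold with 2 false among 113 calls. In jejunum ILC3 against ILC1 (14098 genes) it recovered 0, 12, 64 and 74% with 1 false among 76, and in lung against spleen ILC2 (14234 genes) 2, 2, 20 and 46% with 1 false among 36. In the same order DESeq2 had 33 false of 158 calls, 24 of 122 and 22 of 85, limma-trend 3 of 108, 10 of 91 and 42 of 92, and edgeR with the donor as a block 2 of 107, 2 of 71 and 0 of 24. camera called the list that was moved each time and 0, 2 and 0 of 20 unmoved lists. Simulated genes were drawn independently and without a donor effect. False list calls from correlated genes, and the use of a donor block, were therefore not tested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6. A principal component analysis of the 1000 most variable genes gave 30.4, 15.5 and 12.7% of the variance to the first 3 components.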

Results

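RNA of innate lymphoid cells (ILCs) and natural killer (NK) cells from human spleen, jejunum and lung was measured by Smart-seq2, a full-length cDNA protocol for small amounts of RNA, and deposited as read counts per gene symbol. The labels divide the cells into NK cells (cytotoxic lymphocytes), ILC1 (helper-like ILCs that make interferon-gamma), ILC2 (type 2 cytokine producers) and ILC3 (producers of IL-17 and IL-22). The 92 libraries used here came from 5 donors, with repeat libraries of the same donor, tissue and cell type. Spleen gave 15 NK, 13 ILC1 and 14 ILC3 libraries, each from 5 donors, and 5 ILC2 libraries from 2 donors. Jejunum gave 15 NK libraries from 5 donors, 12 ILC1 libraries from 4 and 9 ILC3 libraries from 3. Lung gave 6 ILC2 libraries from 2 donors. Lung ILC3 (2 libraries) and lung NK (1 library) came from 1 donor each and entered no test. Total counts per library ranged from 169417 to 1630063 (median 684141). Repeat libraries were summed per donor, tissue and cell type, which gave 33 sums with totals of 595449 to 4291274 (median 1989498). The donor was the replicate. Levels are CPM, given as mean ± SD over donors. For single genes the total was that of the tested genes times its TMM factor, and for summed marker lists it was the plain total of all genes, so the 2 kinds of level are on different scales. Repeat libraries correlated across genes with a median Spearman rho of 0.849 (86 pairs). The median was 0.765 for libraries of the same group from other donors (421 pairs). It was 0.741 for the same donor in other groups (747 pairs) and 0.716 for other groups and donors (2932 pairs). Every gene named by rank in a comparison of groups had each donor on the side of the change from the other group's mean log2 level. Genes named in interactions were not held to this.

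**Figure D1:**
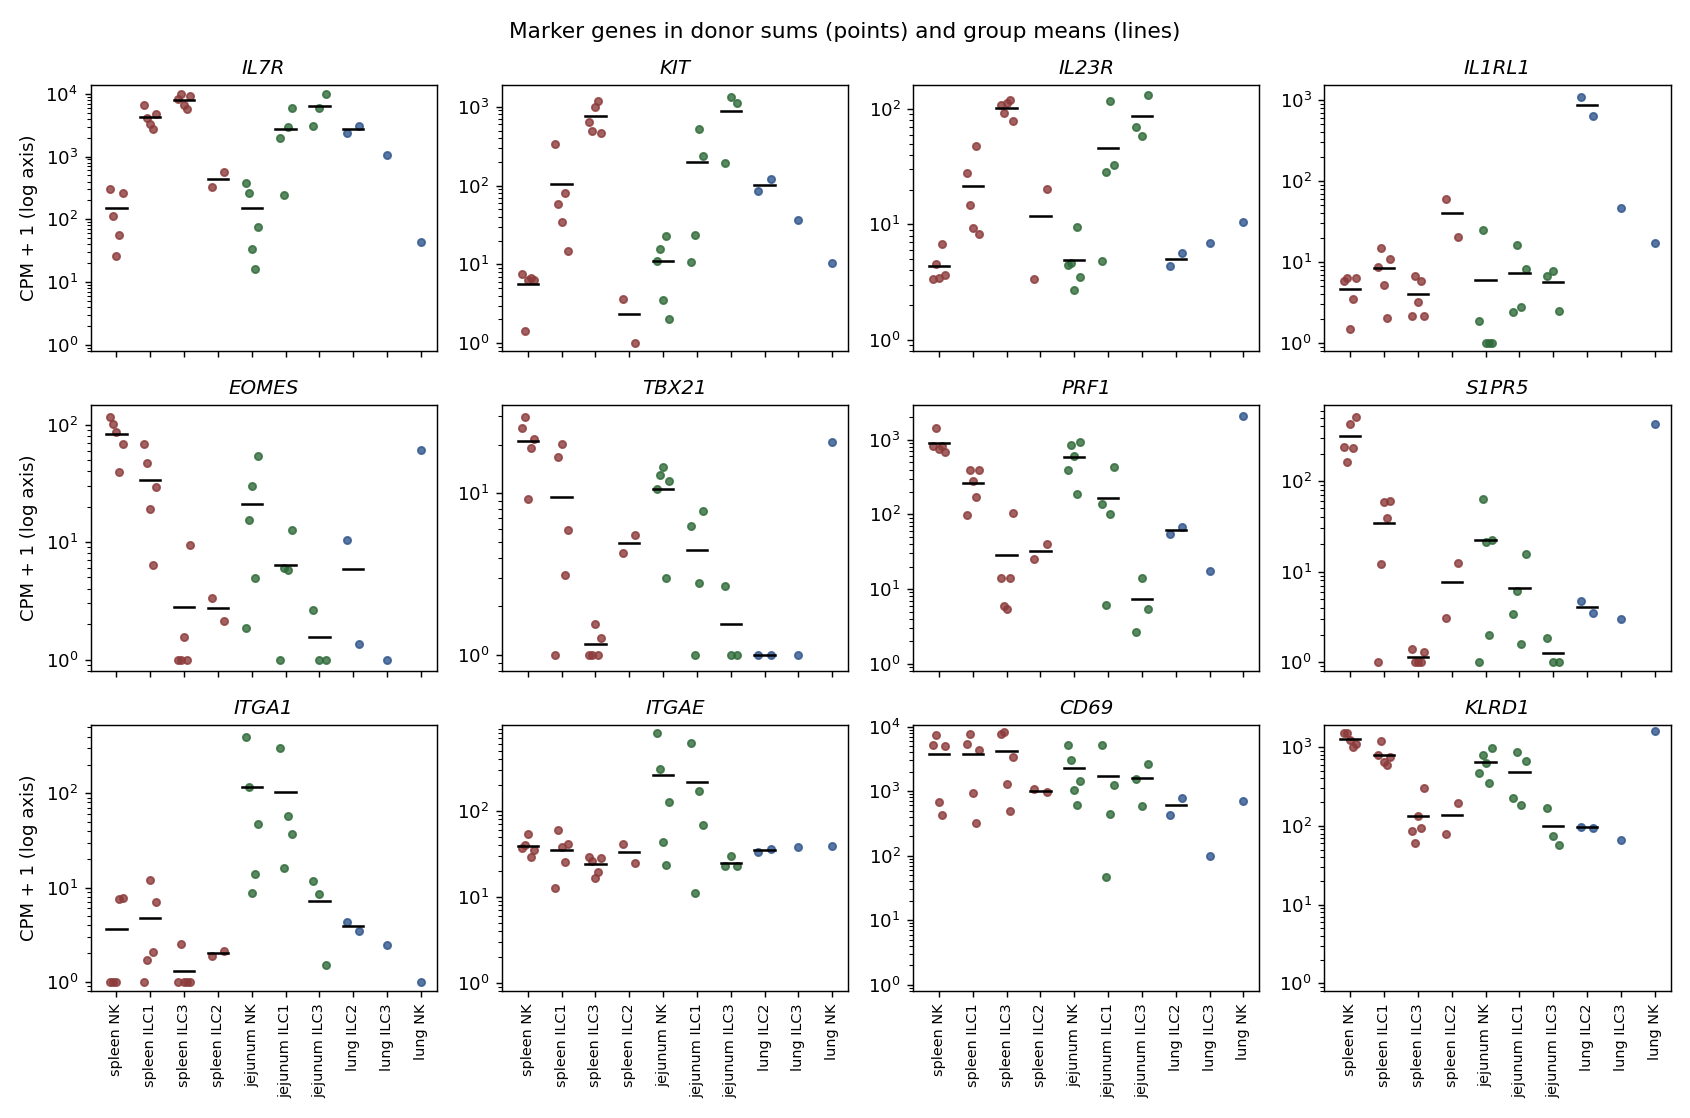
CPM + 1 (log axis) of 12 marker genes in the 10 tissue and cell type groups. Points are donor sums and lines are group means, and IL7R averaged 4287 CPM in spleen ILC1 and 7969 CPM in spleen ILC3 against 152 CPM in spleen NK.

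Spleen ILC1 and spleen NK cells were compared to find what parts helper-like cells from killer cells within an organ. Spleen ILC1 carried more mRNA of IL7R, the interleukin 7 receptor that marks helper ILCs, at 4287 ± 1458 CPM against 152 ± 126 CPM in NK cells (28.1-fold, n = 5 and 5, edgeR adjusted p = 0.00667). CCR6, a chemokine receptor of ILC3 and B cells, rose 6.19-fold from 16.1 ± 8.76 to 100.5 ± 48.6 CPM (edgeR adjusted p = 0.024). In all, 7 genes were higher in ILC1 (AFF3, IL7R, SAMD4A, CCR6, ZC2HC1A, CCSER1 and ADRBK2) and 1 was lower, TKTL1, a transketolase-like gene at 0.289 ± 0.479 against 27.7 ± 12.5 CPM (ratio of pooled counts 70.0, 95% counting interval 23.7 to 342, edgeR adjusted p = 0.0367). Genes of the type 3 program, which ILC3 use, rose as a list (median log2 fold change 2.60, or 2.58 with unseen genes at their bound, camera adjusted p = 3.58e-12). Of its 18 members 1 passed over all genes and 8 when adjusted over the list alone. Among these were KIT, the stem cell factor receptor (105 ± 134 CPM, median 57.3 and 1 sum at 339.9, against 4.68 ± 2.42 CPM), and IL1R1, an interleukin 1 receptor (148 ± 168 against 3.79 ± 3.55 CPM). The sort gates are not given, so whether IL7R or KIT served to sort the groups is not known. A gene used to sort would differ by design, here and in the other comparisons of cell types.

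Genes of the cytotoxic machinery fell in spleen ILC1 as a list (median log2 fold change -1.76, camera adjusted p = 6.69e-16), with 9 of 15 members lower when adjusted over the list alone and none over all genes. GZMB, a granzyme protease, was at 30.2 ± 39.4 against 329 ± 74.2 CPM and PRF1, the pore former perforin, at 266 ± 132 against 902 ± 298 CPM. The killer cell immunoglobulin-like receptors (KIR) fell too, with 4 of 5 members lower when adjusted over the list alone (median -2.99, camera adjusted p = 1.69e-12). S1PR5, a receptor for exit from tissue, fell when adjusted over its list alone (33.4 ± 27.1 against 311 ± 145 CPM). The NK and ILC1 master regulators EOMES (32.9 ± 24.1 against 81.3 ± 29.6 CPM) and TBX21 (8.43 ± 8.57 against 19.99 ± 7.69 CPM) did not pass. Helper ILC genes (median 0.20, 4 of 12 higher and RORA lower when adjusted over the list alone, camera adjusted p = 0.0193), type 2 genes (1.48, 0.0275), ribosomal protein genes (0.73, 2.86e-10), NK receptors (-0.68, 3.04e-05), type 1 genes (-0.56, 0.00649), immediate early genes (-0.45, 0.0491) and proliferation genes (-1.11, 9.41e-05) were also called. None of these 7 held with an estimated correlation (adjusted p = 0.33, 0.27, 0.507, 0.388, 0.507, 0.864 and 0.27 in that order). Markers of B and plasma cells moved with these groups, at a summed 956 ± 865 CPM in ILC1 and 299 ± 431 CPM in NK cells. They were called as a list (median log2 fold change 3.80, 6 of 9 higher when adjusted over the list alone, camera adjusted p = 1.51e-07, and adjusted p = 0.196 with an estimated correlation). With the donor as a block the counts were 39 higher and 9 lower. RLE scaling gave 3 genes, DESeq2 130 (104 higher, 26 lower), limma-trend 39 (18 higher, 21 lower) and the fit without 2 jejunum sums that stood apart 14. Leaving out each of the 5 donors in turn gave 2, 1, 3, 0 and 7 genes. TKTL1 lost its call with RLE scaling and when donor 1, 2, 3 or 4 was left out, where no gene was lower.

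Spleen ILC3 differed from spleen NK cells in 507 genes, 269 higher and 238 lower (n = 5 and 5). ILC3 carried the receptors of the type 3 program. KIT stood at 753 ± 321 against 4.68 ± 2.42 CPM (log2 fold change 7.33 ± 0.91 SE, edgeR adjusted p = 2.49e-04). IL1R1 stood at 762 ± 284 against 3.79 ± 3.55 CPM and IL23R, the interleukin 23 receptor, at 102 ± 16.5 against 3.36 ± 1.43 CPM (30.6-fold, edgeR adjusted p = 8.17e-05). AHR, a sensor of dietary ligands, rose by 2.24 on the log2 scale. In this list 12 of 18 members were higher over all genes and 14 when adjusted over the list alone (median log2 fold change 4.49, or 4.11 with unseen genes at their bound, camera adjusted p = 8.26e-21). IL22, the cytokine of ILC3, had no read in NK cells and was at least 18.1-fold higher in ILC3, when adjusted over the list alone. Genes shared by helper ILCs rose (3 of 12 over all genes, 6 when adjusted over the list alone, median 1.52, camera adjusted p = 3.9e-06), led by IL7R (7969 ± 1755 against 152 ± 126 CPM, 52.3-fold). Other genes with the smallest p among those higher were AFF3, SSBP2, SAMD4A, MPV17L, SOX4, SLC40A1, LDLRAD3, CCR6 and GNAI1.

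Genes of the cytotoxic program were lower in spleen ILC3, 10 of 15 members over all genes and 12 when adjusted over the list alone (median log2 fold change -5.87, camera adjusted p = 1.07e-25). CST7, an inhibitor of lysosomal proteases, fell from 322 ± 101 to 4.39 ± 5.36 CPM (69.8-fold), PRF1 from 902 ± 298 to 27.9 ± 42.8 CPM (median 12.9, with 1 sum at 104) and FASLG, a death ligand, from 85.2 ± 31.4 to 0.113 ± 0.252 CPM (ratio of pooled counts 523, 95% counting interval 144 to 4322). GNLY, which encodes granulysin, did not pass (271 ± 204 against 790 ± 257 CPM). NK receptors fell in 8 of 17 members over all genes and 14 when adjusted over the list alone (median -2.20, camera adjusted p = 1.95e-17), and all 5 KIR fell (median -6.94, camera adjusted p = 6.24e-15). Type 1 genes fell in 7 of 17 members over all genes and 11 over the list alone (median -2.54, camera adjusted p = 1.69e-12). Among them were EOMES (1.8 ± 3.72 against 81.3 ± 29.6 CPM), TBX21 (0.168 ± 0.249 against 19.99 ± 7.69 CPM) and IFNG, the gene of interferon-gamma, which fell by 5.45 on the log2 scale. IL18R1, a receptor for interleukin 18, rose by 1.69 when adjusted over that list alone. S1PR5 (0.133 ± 0.186 against 311 ± 145 CPM), SLAMF7, GPR56, CD247, RASGRP1, MCTP2, KLRD1, TENM1, IKZF3 and GZMM completed the 12 genes with the smallest p among those lower. Within other lists CCR4, a chemokine receptor of type 2 cells, rose by 6.09, IFI44 and IFI44L rose by 2.28 and 4.30, and MKI67, a proliferation marker, fell by 6.52, all over all genes. Residency genes (4 of 14 lower over all genes, median -0.78, camera adjusted p = 0.00454), proliferation genes (1 of 15 lower over all genes and 5 over the list alone, -2.63, 2.15e-07), ribosomal protein genes (0.49, 2.39e-04) and T cell markers (-0.30, 0.0471, and 0.0596 with the donor as a block) were called. These 4 were lost with an estimated correlation (adjusted p = 0.196, 0.11, 0.82 and 0.511). The erythroid markers, a list that was not called here (camera adjusted p = 0.486), stood at 312 ± 698 CPM in ILC3 through 1 sum at 1560 CPM, and at 1.56 ± 2.27 CPM in NK cells. The block gave 362 higher and 328 lower genes, and DESeq2 gave 889. Leaving out a donor gave 346, 303, 308, 339 and 335.

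The same organ allowed ILC3 to be set against ILC1. Only SORT1, a sorting receptor, was higher in spleen ILC3 among single genes over all genes tested (56.3 ± 25.2 against 4.74 ± 4.65 CPM, log2 fold change 3.54 ± 0.64 SE, edgeR adjusted p = 0.0165), and 20 genes were lower. The lower ones held cytotoxic and NK genes: CST7 (4.39 ± 5.36 against 118 ± 47.1 CPM, 25.6-fold, edgeR adjusted p = 0.00312), KLRD1, the CD94 subunit of NK receptors (134 ± 97.4 against 795 ± 242 CPM, 5.91-fold). CD247, a signaling chain of NK and T cell receptors (8.97 ± 5.17 against 70.5 ± 28.96 CPM), was lower too, as were TBX21 (ratio of pooled counts 67.4, 95% counting interval 18.2 to 565) and the gut homing receptor GPR15 (no read in ILC3, at least 84.1-fold lower). FASLG, SLAMF7, TENM1, IKZF3, LYST, KLRC4, KLRC2 and PYHIN1 were lower as well. Type 3 genes were higher as a list (median 1.81, camera adjusted p = 5.87e-15), with none passing over all genes and 6 of 18 when adjusted over the list alone, among them AHR, IL1R1, IL23R, IL4I1 and KIT. Cytotoxic genes (3 of 15 over all genes, 7 over the list alone, median -2.23, camera adjusted p = 4.13e-16), KIR (2 and 4 of 5, -4.15, 5.57e-08) and type 1 genes (2 and 11 of 17, -1.91, 1.18e-13) fell and held with an estimated correlation.

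NK receptors (2 of 17 over all genes, 7 over the list alone, median -1.66, camera adjusted p = 4.45e-14), helper ILC genes (0.91, 5.37e-05), residency genes (-0.60, 0.00769), immediate early genes (0.55, 0.013), proliferation genes (-1.07, 0.00651) and T cell markers (-0.76, 0.00397) were called between spleen ILC3 and ILC1. All 6 were lost with an estimated correlation (adjusted p = 0.0623, 0.0636, 0.237, 0.777, 0.507 and 0.27). Markers of B and plasma cells were lower in ILC3, at 89.3 ± 101 against 956 ± 865 CPM (8 of 9 when adjusted over the list alone, median -3.42, camera adjusted p = 2.09e-10, and adjusted p = 0.104 with an estimated correlation). Erythroid markers were called only with the donor as a block (0.0252 against 0.227), and not with the block and an estimated correlation (0.432). The block gave 13 higher and 52 lower genes, DESeq2 53 and 102, and limma-trend 76 and 51, with more genes higher than lower in the last. The fit without the 2 jejunum sums that stood apart gave 38. In turn, leaving out each of the 5 donors gave 7, 0, 4, 4 and 26 genes.

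ILC2 of spleen came from 2 donors, so the comparison with the other spleen ILCs rests on few samples. Against spleen ILC3, edgeR called 0 genes (2100 had an unadjusted p under 0.05), while DESeq2 called 403 (139 higher, 264 lower) and limma-trend 453 (335 higher, 118 lower). By list, type 2 genes were higher in spleen ILC2 (median log2 fold change 2.82, or 2.73 with unseen genes at their bound, camera adjusted p = 0.0038, and adjusted p = 0.123 with an estimated correlation). Of 12 members 6 were higher and 2 lower when adjusted over the list alone. IL1RL1, the receptor for interleukin 33, stood at 38.8 ± 27.5 against 3.01 ± 2.14 CPM. PPARG, a lipid-sensing transcription factor, stood at 10.2 ± 0.14 against 0.225 ± 0.503 CPM. IL13, a type 2 cytokine, stood at 3.25 ± 4.60 CPM against no read (at least 15.8-fold), with its reads in a single spleen ILC2 sum. GATA3, the transcription factor of ILC2, was lower, at 19.7 ± 10.8 against 61.1 ± 8.73 CPM. So was AREG, which encodes amphiregulin (-2.98 on the log2 scale). Type 3 genes fell in 12 of 18 members over the list alone (median -4.57, or -3.94 at the bounds, camera adjusted p = 9.42e-12), with KIT at 1.33 ± 1.88 against 753 ± 321 CPM. Helper ILC genes fell in 10 of 12 members over the list alone (median -3.36, or -3.10 at the bounds, camera adjusted p = 1.07e-09), with IL7R at 440.4 ± 168 against 7969 ± 1755 CPM and ID2, a regulator all ILCs need, at 82.6 ± 13.6 against 1023 ± 409.8 CPM.

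Markers of other cells moved with these groups in spleen ILC2. Myeloid markers summed to 8894 ± 6584 CPM in ILC2 and 1181 ± 2311 CPM in ILC3, where the median was 49.6 and 1 sum, at 5299, lay above the lower ILC2 sum of 4239 (median log2 fold change 2.91, camera adjusted p = 1.26e-12). B and plasma cell markers summed to 1739 ± 1498 and 89.3 ± 101 CPM (4.76, 8 of 9 over the list alone, 2.03e-09) and plasmacytoid dendritic markers to 51.5 ± 9.58 and 4.98 ± 5.74 CPM (3.93, 3 of 3 over the list alone, 8.72e-05). With an estimated correlation the adjusted p was 0.146, 0.125 and 0.00957. NK receptors (-1.72, 0.0307), immediate early genes (-1.04, 0.0135), proliferation genes (1.35, 0.0151), glycolysis genes (1.003, 2.69e-04, with HK2 and PKM higher over the list alone) and ribosomal protein genes (0.86, 2.77e-05) were called. Each was lost with an estimated correlation (adjusted p = 0.746, 0.778, 0.588, 0.274 and 0.754). The donor block gave 9 higher and 37 lower genes between spleen ILC2 and ILC3, RLE scaling 8, no filter 1, and the fits without the 2 jejunum sums that stood apart and without the 3 jejunum NK sums rich in plasma cell RNA 203 and 12. Leaving out each of the 5 donors in turn gave 0, 0, 167, 1 and 12 genes. A lone remaining donor was then assumed to vary like the other groups.

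Against spleen ILC1, 1 gene was lower in spleen ILC2, DHRS3, a retinal reductase (6.79 ± 1.66 against 151 ± 38.3 CPM, log2 fold change -4.51 ± 0.65 SE, edgeR adjusted p = 0.0418), and none was higher. NK receptors fell in 12 of 17 members over the list alone while TYROBP, an adaptor that myeloid cells share, rose (median -3.38, camera adjusted p = 2.99e-14). Helper ILC genes fell in ID2, IL7R, KLRB1 and ZBTB16 over the list alone (median -2.20, camera adjusted p = 2.34e-06). Both lists held with an estimated correlation, as did plasmacytoid dendritic markers (4.42, 5.71e-05). Type 1 genes (5 of 17 over the list alone, -1.74, 7.41e-08), type 3 genes (4 of 18, -2.66, or -2.08 at the bounds, 2.75e-04), cytotoxic genes (-1.92, 1.41e-06), KIR (-1.54, 0.00727), residency genes (-0.51, 0.0128) and type 2 genes (1.13, 0.0432) were called. These were lost with an estimated correlation (adjusted p = 0.095, 0.147, 0.226, 0.269, 0.264 and 0.315). Type 2 genes were also not called without the 2 jejunum sums that stood apart (adjusted p = 0.068) or the 3 rich in plasma cell RNA (0.0562).

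Myeloid markers (8894 ± 6584 in spleen ILC2 against 507 ± 549.9 CPM in spleen ILC1, median 3.86, camera adjusted p = 4.13e-16) and B and plasma cell markers (1739 ± 1498 against 956 ± 865 CPM, 1.20, 0.0151, and 0.957 with the donor as a block) moved with them. So did glycolysis genes (0.71, 4.23e-04, with ALDOA, HK2 and PKM higher over the list alone), oxidative phosphorylation genes (0.58, 0.0436, and 0.0798 without the 3 jejunum NK sums) and ribosomal protein genes (0.63, 1.57e-05). All 5 lost the call with an estimated correlation (adjusted p = 0.0924, 0.717, 0.30, 0.842 and 0.75). The block called immediate early genes (0.0266 against 0.339, and 0.733 with an estimated correlation), and its counts were 1 higher and 8 lower. DESeq2 gave 159 genes (47 higher, 112 lower), limma-trend 209 (189 higher, 20 lower), RLE scaling 2, no filter 2, and the fits without the 2 apart and the 3 plasma-rich jejunum sums 11 and 2. In turn, leaving out each of the 5 donors gave 0, 0, 1, 3 and 0 genes, and DHRS3 was among none of them.

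**Figure D2:**
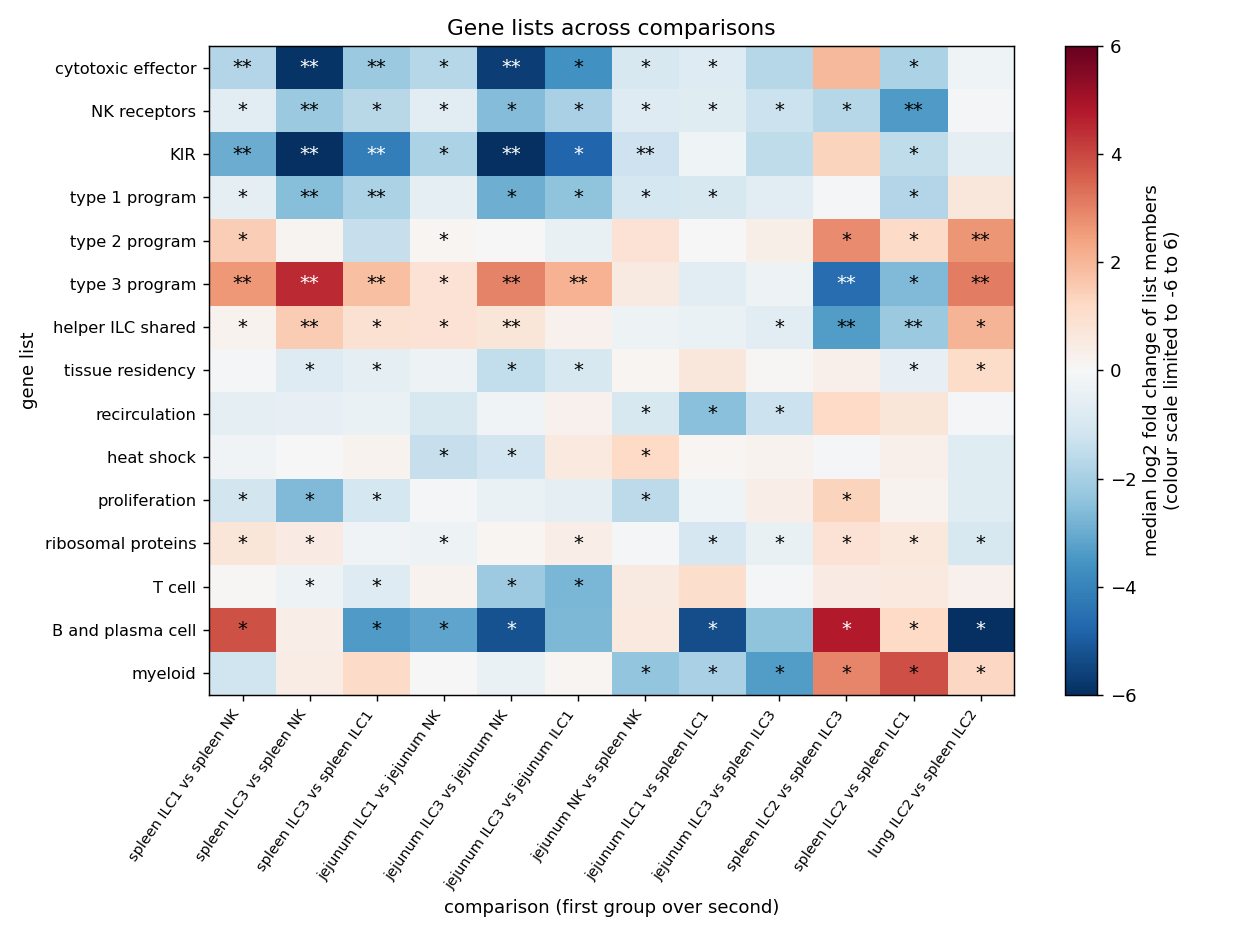
Median log2 fold change (color, first group over second) of 15 gene lists in 12 comparisons. A star marks a camera adjusted p under 0.05 with the preset correlation and a double star one that also held with the estimated correlation, and the type 3 list had medians of 4.49 in spleen ILC3 and 2.997 in jejunum ILC3 against NK cells.

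In jejunum, ILC1 were set against NK cells to see whether the same divide holds in the gut. edgeR called 0 genes (n = 4 and 5, 1972 genes with an unadjusted p under 0.05, limma-trend 0, DESeq2 1032). IL7R stood at 2787 ± 2398 CPM in jejunum ILC1 and 152 ± 159 CPM in NK cells (log2 fold change 4.20 ± 0.73 SE), which missed the threshold over all genes (edgeR adjusted p = 0.0663) and passed when adjusted over the list alone (1.1e-04). With the donor as a block IL7R was higher over all genes (adjusted p = 0.0121) and PELI1, a ubiquitin ligase, lower (0.0299). Type 3 genes rose as a list (5 of 18 over the list alone, median 0.87, camera adjusted p = 6.06e-05), among them IL23R, CCR6 and KIT (197 ± 240.2 against 9.96 ± 8.59 CPM). Helper ILC genes rose (2 of 12 over the list alone, 0.89, 2.46e-04). Cytotoxic genes fell (none over the list alone, -1.73, or -1.37 with unseen genes at their bound, 9.39e-10), as did NK receptors (-0.63, 4.81e-04) and KIR (KIR3DL1 over the list alone, -1.91, 0.00198). None of these 5 held with an estimated correlation (adjusted p = 0.107, 0.10, 0.104, 0.507 and 0.196). The NK receptor call was also lost without the 2 sums that stood apart (adjusted p = 0.0963), and the type 3 call without the 3 plasma-rich NK sums (0.103).

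Plasma cell RNA was high in jejunum NK sums: IGJ, the joining chain of secreted antibodies, stood at 33410 ± 33140 CPM in NK cells and 868 ± 1201 CPM in jejunum ILC1 (TMM-scaled, unlike list sums). The B and plasma cell list was lower in ILC1 (3 of 9 over the list alone, median -3.17, camera adjusted p = 0.0328). Heat shock genes moved with it (-1.37, 4.13e-07), as did stromal markers (-1.90, 0.0135), immediate early (-0.47, 0.00649), glycolysis (-0.42, 0.0117), oxidative phosphorylation (-0.34, 0.00737), ribosomal protein (-0.31, 3.18e-06) and type 2 genes (0.13, or 0.04 at the bounds, 0.0491). None of these 8 held with an estimated correlation (adjusted p = 0.758, 0.388, 0.666, 0.75, 0.523, 0.729, 0.72 and 0.337) or without the 3 plasma-rich NK sums (0.197, 0.812, 0.139, 0.0683, 0.15, 0.392, 0.253 and 0.533). The last 5 were also not called without the 2 sums that stood apart (0.0509, 0.653, 0.811, 0.518 and 0.0803). RLE scaling moved the median log2 fold change of all genes from -0.07 to 0.06 in this comparison, from -0.03 to -0.17 for jejunum ILC3 over ILC1 and from 0.05 to 0.22 for jejunum over spleen ILC1. It called 823 genes here, 786 higher and 37 lower. No filter called 4 genes and the fit without the 2 apart sums 1. Leaving out each of the 5 donors in turn gave 0, 2, 0, 0 and 0 genes.

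Jejunum ILC3 differed from jejunum NK cells in 86 genes, 40 higher and 46 lower (n = 3 and 5). IL7R was 41.8-fold higher (6358 ± 3524 against 152 ± 159 CPM, edgeR adjusted p = 0.00183). KIT stood at 878 ± 603 against 9.96 ± 8.59 CPM (log2 fold change 6.44 ± 0.995 SE, edgeR adjusted p = 0.00374) and IL23R at 86.7 ± 40.1 against 3.94 ± 2.62 CPM (edgeR adjusted p = 0.00184). Type 3 genes were higher in 7 of 18 members over all genes and 11 when adjusted over the list alone (median 2.997, camera adjusted p = 1.78e-19), and helper ILC genes in 2 and 3 of 12 (0.75, 1.66e-06). AFF3, MPV17L, SVIL, IFI44 (an interferon-induced gene, 13.2-fold), TNFRSF25, TNFRSF11A (the RANK receptor), CERK, KIAA1324 and CEACAM1 were the other higher genes with the smallest p. PRF1 was 89.0-fold lower in ILC3 (6.34 ± 5.83 against 596 ± 312 CPM, edgeR adjusted p = 0.00488), CST7 111-fold lower (1.5 ± 0.995 against 163 ± 93.0 CPM) and PRDM1, a transcriptional repressor, 16.3-fold lower (22.5 ± 6.42 against 369 ± 187 CPM). Plasma cells express PRDM1 too, and the NK sums held 29680 ± 28320 CPM of B and plasma cell markers. The PRDM1 level of NK sums may thus hold their RNA. Cytotoxic genes fell in 6 of 15 members over all genes and 12 over the list alone (median -5.64, camera adjusted p = 1.05e-17) and KIR in 3 and 5 of 5 (-6.50, or -5.67 at the bounds, 6.28e-09). All 4 of these lists held with an estimated correlation. SLAMF7, CD247, SLA2, KLRC4, LAT, APOBEC3C, APOBEC3G, MCTP2 and CCL3L3 completed the lower genes.

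NK receptors (5 of 17 lower in jejunum ILC3 over all genes, 13 over the list alone, median -2.61, camera adjusted p = 1.18e-13), type 1 genes (1 and 11 of 17 lower, with IL18R1 higher over the list alone, -2.94, 6.28e-09), residency genes (ITGA1, ITGAE and PRDM1 lower over the list alone, -1.49, 8.5e-04) and T cell markers (-2.18, 0.0206) were called. Their calls were lost with an estimated correlation (adjusted p = 0.0636, 0.0636, 0.123 and 0.404). B and plasma cell markers were at 31.0 ± 12.8 CPM in jejunum ILC3 and 29680 ± 28320 CPM in NK cells (-5.24, or -2.86 at the bounds, 0.00822), and heat shock genes were lower too (-1.16, 0.00364). Neither held with an estimated correlation (adjusted p = 0.666 and 0.75), without the 2 jejunum sums that stood apart (0.0829 and 0.716) or without the 3 plasma-rich NK sums (0.933 and 0.613). Intestinal epithelial markers were at 1729 ± 2881 CPM in ILC3, where 1 sum at 5055 CPM carried the mean, and 397 ± 516 CPM in NK cells (medians 72.3 and 175.5). They were called only with the donor as a block (0.0195 against 0.951, and 0.739 with the block and an estimated correlation). The block gave 65 higher and 75 lower genes, and DESeq2 106 and 227. The fit without the 3 plasma-rich NK sums gave 3 higher and 27 lower, 22 of these 30 shared. In turn, leaving out each of the 5 donors gave 91, 32, 72, 36 and 7 genes.

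Between jejunum ILC3 and jejunum ILC1 the list of type 3 genes was higher in ILC3 and 2 genes were lower. CST7 was lower in ILC3 (1.5 ± 0.995 against 65.9 ± 58.9 CPM, log2 fold change -5.52 ± 0.96 SE, n = 3 and 4), and so was CD247 (4.52 ± 2.53 against 100.4 ± 82.0 CPM, -4.42 ± 0.73 SE), both at an edgeR adjusted p of 0.0488. CD247 fell outside the rule for named genes and was added after its values were seen. No gene was higher. The type 3 list (median 2.08, camera adjusted p = 5.92e-11) had 3 of 18 members passing over the list alone, IL1R1 and TNFSF4 among them, and held with an estimated correlation. Cytotoxic genes (7 of 15 lower over the list alone, -3.65, 1.71e-07), NK receptors (8 of 17, -1.97, 1.43e-07), KIR (4 of 5, -4.75, or -4.19 at the bounds, 7.49e-05), type 1 genes (5 of 17, -2.43, 1.68e-07), T cell markers (3 of 9, -2.73, or -2.72 at the bounds, 8.63e-06) and residency genes (3 of 14, -0.95, 0.0208) were called. An estimated correlation ended all 6 calls (adjusted p = 0.193, 0.226, 0.0891, 0.104, 0.0636 and 0.33). ITGA1, an integrin of resident lymphocytes, was at 6.28 ± 5.26 against 102 ± 133 CPM. Oxidative phosphorylation (0.52, 8.73e-04) and ribosomal protein genes (0.40, 3.26e-08) lost the call with an estimated correlation (adjusted p = 0.592 for both) and without the 2 sums that stood apart (0.77 and 0.739). The block called helper ILC genes (0.0456), heat shock genes (2.2e-07) and NF-kB genes (0.0145) as well, at 0.0739, 0.254 and 0.206 without it and 0.369, 0.261 and 0.446 with it and an estimated correlation. The block gave 1 higher and 7 lower genes, DESeq2 269, limma-trend 5 (none shared), and leaving out each of the 5 donors in turn 1, 0, 2, 0 and 0.

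Jejunum and spleen NK cells were compared to ask how far an NK cell differs by tissue. In jejunum NK cells 20 genes were higher and 4 lower (n = 5 and 5). CD9, a tetraspanin of adhesive cells, was 47.1-fold higher (86.1 ± 75.9 against 1.83 ± 1.25 CPM, edgeR adjusted p = 0.00946), INSR, the insulin receptor, 18.9-fold (92.3 ± 109 against 4.62 ± 3.56 CPM, edgeR adjusted p = 0.00352). KLHL6, a gene of lymphocyte signaling, was 5.85-fold higher (234 ± 127 against 39.8 ± 15.1 CPM) and RAB3GAP1, a regulator of membrane traffic, 8.18-fold (edgeR adjusted p = 0.00214 for both). DERL3 and FKBP2, genes of the endoplasmic reticulum, MGLL, PPAP2A, SPINT2, PRKAR2B, CLIC5 and ZC2HC1A were also higher. PIK3R5, a kinase subunit, was 5.05-fold lower (43.9 ± 19.6 against 222 ± 57.7 CPM, edgeR adjusted p = 0.0156), with LYST, ARRDC2 and CEP78. No gene was lower without the 3 plasma-rich NK sums, nor when donor 1, 4 or 5 was left out. Of the residency list, CD9 rose over all genes and ITGA1 (115 ± 161 against 2.67 ± 3.65 CPM) and ITGAE (261 ± 325 against 37.9 ± 8.99 CPM), integrins that hold lymphocytes in epithelium, when adjusted over the list alone. The list as a whole was not called (median 0.14, camera adjusted p = 0.63). ITGAE ranged from 22.3 to 806 CPM over the jejunum NK sums (median 125). It ranked in the same order as the summed T cell markers (67.5 to 945 CPM, 375 ± 350 in jejunum and 346 ± 87.4 in spleen NK cells). That list holds CD247, a chain that NK cells use as well, so its sum is not RNA of T cells alone. On the single-gene scale CD247 averaged 117 CPM in jejunum and 170 CPM in spleen NK cells. CD69, another residency gene, was at 2254 ± 1852 against 3775 ± 3100 CPM. The recirculation list fell (median -0.98, camera adjusted p = 6.12e-07, and adjusted p = 0.0636 with an estimated correlation), with 2 of 12 members lower over the list alone, S1PR5 (21.1 ± 25.4 against 311 ± 145 CPM) among them.

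KIR were lower in jejunum NK cells as a list, none of the 5 over its members alone (median -1.25, camera adjusted p = 9.25e-06), and held with an estimated correlation (0.045). Cytotoxic genes (-0.98, 2.43e-08), NK receptors (-0.76, 2.69e-08), type 1 genes (-1.06, 5.49e-05), proliferation genes (-1.56, 1.11e-05), myeloid markers (-2.35, 0.035) and heat shock genes (1.20, 7.2e-06, with HSPA5 and HSPB1 higher over the list alone) were called. They were lost with an estimated correlation (adjusted p = 0.14, 0.196, 0.237, 0.196, 0.864 and 0.482). The heat shock call was also lost without the 3 plasma-rich sums (adjusted p = 0.899, median 0.12), and so was the NK receptor call (0.097). The myeloid call was lost without the 2 jejunum sums that stood apart (0.0509). Intestinal epithelial and stromal markers were higher. The epithelial list stood at 397 ± 516 against 53.7 ± 24.3 CPM (10 of 14 over the list alone, median 6.39, or 4.90 at the bounds, camera adjusted p = 2.66e-05). The stromal list stood at 369 ± 357 against 59.4 ± 21.8 CPM (8 of 13, 5.66, or 4.92 at the bounds, 7.77e-04). The adjusted p with an estimated correlation was 0.523 and 0.474. B and plasma cell markers stood at 29680 ± 28320 against 299 ± 431 CPM, with CD79A, IGJ and MZB1 higher over the list alone and the list not called (0.61, 0.665). The block gave 75 higher and 20 lower genes, DESeq2 280, limma-trend 71 and the fit without the 2 apart sums 144, while without the 3 plasma-rich sums 18 genes were called, 6 of them shared. Leaving out each of the 5 donors in turn gave 15, 13, 3, 0 and 4 genes.

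**Figure D3:**
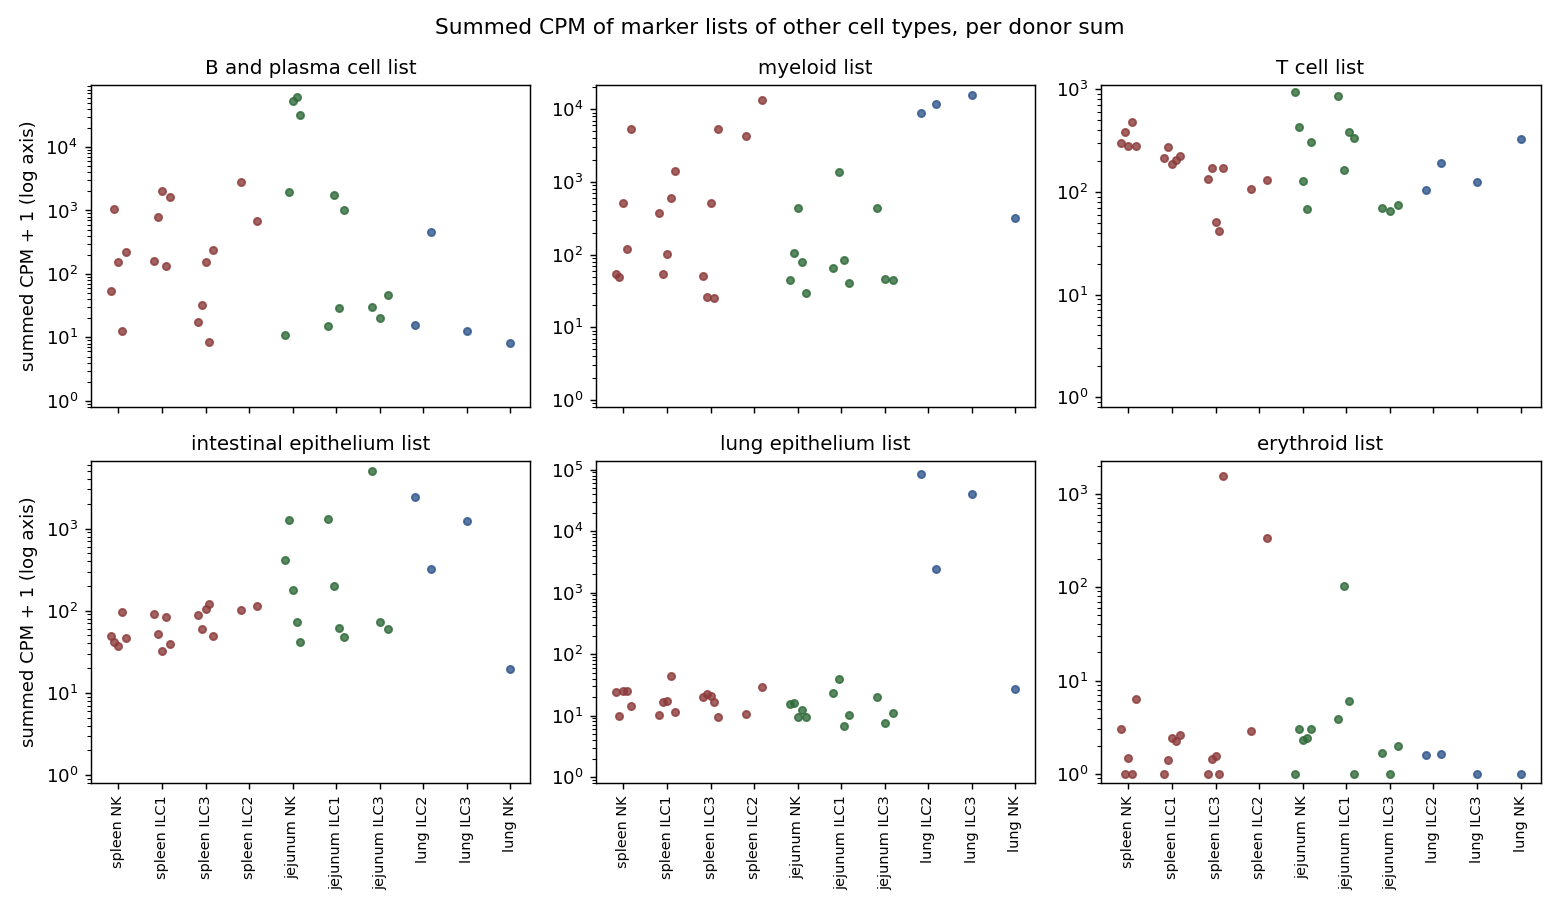
Summed CPM + 1 (log axis) of 6 lists of markers of other cell types in each donor sum, by tissue and cell type. B and plasma cell markers averaged 29680 CPM in jejunum NK, and lung epithelial markers averaged 44510 CPM in lung ILC2 against 18.8 CPM in spleen ILC2.

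For ILC1 the same question of tissue gave 0 genes in edgeR between jejunum and spleen (n = 4 and 5, 2330 genes with an unadjusted p under 0.05, limma-trend 9, DESeq2 1203 with 1029 higher and 174 lower, RLE scaling 723 with 674 higher and 49 lower). Over the residency list alone ITGA1 (102 ± 133 against 3.75 ± 4.68 CPM), ITGAE (216 ± 276 against 34.3 ± 17.8 CPM), CD9 and CD101, an inhibitory receptor, were higher in jejunum ILC1 and KLRC1 lower, with the list not called (median 0.68, camera adjusted p = 0.559). ITGA1 (15.1 to 299 CPM, median 46.3) and ITGAE (10.1 to 618 CPM, median 118) were highest in the jejunum ILC1 sum with the most T cell marker RNA, and both ranked in the same order as that RNA (161 to 853 CPM) over the 4 sums. Recirculation genes fell (median -2.50, camera adjusted p = 1.15e-05), with 1 of 12 members lower over the list alone. Ribosomal protein genes were lower in all 27 members over the list alone (-1.03, 2.99e-27). Cytotoxic genes (-0.79, or -0.73 at the bounds, 3.81e-04), NK receptors (-0.71, 1.05e-06), type 1 genes (-0.97, 0.00568) and glycolysis genes (-0.50, 0.00336) were lower as lists. None of these 6 held with an estimated correlation (adjusted p = 0.115, 0.133, 0.458, 0.274, 0.507 and 0.438), and glycolysis was not called without the 2 sums that stood apart (0.287). B cell markers were lower in jejunum ILC1 (7 of 9 over the list alone, with IGJ higher, median -5.33, camera adjusted p = 4.5e-08), as were myeloid markers (-1.94, or -1.88 at the bounds, 0.0151). Intestinal epithelial markers were higher (404 ± 607 against 59.2 ± 26.7 CPM, with a median of 130.5 and 1 sum at 1309 in jejunum, 4.89, or 4.74 at the bounds, 1.06e-04). Adjusted p was 0.183, 0.807 and 0.588 for these 3 with an estimated correlation. With the donor as a block 4 genes were higher and 6 lower, and NF-kB genes (-0.33, 0.0197 against 0.205) and T cell markers (1.04, 0.0339 against 0.159) were called. Neither call held with the block and an estimated correlation (0.474 and 0.406).

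For ILC3, edgeR called 0 genes between jejunum and spleen (n = 3 and 5, 1080 with an unadjusted p under 0.05, limma-trend 1, DESeq2 55). CD9 alone of the residency list was higher when adjusted over the list alone (41.4 ± 56.3 against 1.92 ± 2.17 CPM, log2 fold change 4.56 ± 0.99 SE, edgeR adjusted p = 0.24), and ITGAE was level (log2 fold change 0.07). The SD of CD9 exceeded its mean in jejunum, where 1 sum held 5055 CPM of intestinal epithelial markers (others 72.35 and 59.1). Whether CD9 came from epithelium was not tested. Recirculation genes were lower (median -1.29, or -1.14 at the bounds, camera adjusted p = 0.00364), with no member passing over the list alone. NK receptors (-1.27, 5.79e-05), helper ILC genes (-0.69, 0.00804), ribosomal protein genes (-0.47, 1.39e-05) and immediate early genes (-0.53, 0.0071) were lower too. None of these 5 held with an estimated correlation (adjusted p = 0.345, 0.431, 0.269, 0.75 and 0.75), and helper ILC genes were not called without the 2 sums that stood apart (0.131). Intestinal epithelial markers were higher in jejunum ILC3 (1729 ± 2881 against 83.7 ± 29.8 CPM, 11 of 14 over the list alone, 6.68, or 5.79 at the bounds, 5.09e-05). Stromal markers were higher as well (6 of 13, 3.76, or 3.27 at the bounds, 0.00235) and myeloid markers lower (-3.36, or -3.11 at the bounds, 0.0364). For these 3 the adjusted p was 0.548, 0.532 and 0.864 with an estimated correlation. The first pair was not called without the 2 sums that stood apart (0.901 and 0.718, medians at 0). With the donor as a block 3 genes were higher, FABP1, PCK1 and RBP2 (adjusted p = 0.00349 each), which enterocytes express. It also called cytotoxic genes (0.0235), heat shock genes (0.0299), B and plasma cell markers (0.0171), mast cell markers (0.0323) and erythroid markers (0.00644), at 0.214, 0.702, 0.222, 0.109 and 0.184 without it. None of these 5 held with the block and an estimated correlation (0.309 to 0.739).

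Whether the tissue difference itself depended on the cell type was tested by interaction. INSR differed between NK cells and ILC1 (log2 difference -5.45 ± 0.91 SE, edgeR adjusted p = 0.0443). It was higher in jejunum than in spleen in NK cells (log2 fold change 4.24) and not called in ILC1 (-1.21, edgeR adjusted p = 0.389). KLHL6 differed between NK cells and ILC3 (-3.41 ± 0.57 SE, edgeR adjusted p = 0.0434), higher in jejunum NK cells (2.55) and not called in ILC3 (-0.86, edgeR adjusted p = 0.716). These were the only genes called in the first and the second test (1058 and 649 with an unadjusted p under 0.05). INSR was not called with RLE scaling (0 genes), and without the 2 jejunum sums that stood apart 3 other genes were called in its test. KLHL6 was called neither without the low count filter nor without those 2 sums (0 genes each). limma-trend called 0 genes in both tests, as did the fit without the 3 plasma-rich NK sums. Between ILC3 and ILC1 edgeR called 0 genes (504 with an unadjusted p under 0.05, limma-trend 0, DESeq2 15). The donor block gave 7, 1 and 0 genes and DESeq2 25 and 34 in the first 2 tests. In turn, leaving out each of the 5 donors gave 0, 1, 0, 0 and 0 genes in the first, where the 1 was INSR, and 0, 1, 0, 0 and 0 in the second, where the 1 was not KLHL6.

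Lung ILC2 were set against spleen ILC2 (2 donors each, 1 shared) to compare a barrier tissue with a lymphoid organ. All 12 tested type 2 genes had a higher fitted level in lung, none passing over the list alone (2 with the donor as a block), and the list was called (median log2 fold change 2.64, camera adjusted p = 2.1e-10, and 0.00238 with an estimated correlation). IL1RL1 stood at 857 ± 318 against 38.8 ± 27.5 CPM (4.44 ± 1.28 SE, edgeR adjusted p = 0.461), AREG at 1261 ± 422 against 284 ± 43.3 CPM and GATA3 at 56.2 ± 33.0 against 19.7 ± 10.8 CPM. IL17RB, a receptor for interleukin 25, stood at 82.4 ± 36.6 against 10.6 ± 2.13 CPM and PTGDR2, the prostaglandin receptor CRTH2, at 14.4 ± 8.17 against 1.46 ± 0.449 CPM. Mast cells express IL1RL1 as well, and mast cell markers summed to 176 and 34.6 CPM in lung against 3.5 and 11.9 CPM in spleen ILC2. Other cells in the sums of either group and a difference between the tissues cannot be told apart here. Type 3 genes rose in 5 of 18 members over the list alone (median 3.05, camera adjusted p = 9.41e-07), with KIT at 101 ± 25.6 against 1.33 ± 1.88 CPM and CSF2, the gene of GM-CSF, at least 101-fold higher, and held with an estimated correlation (0.045). Helper ILC genes were higher as a list (2.03, camera adjusted p = 0.00477, LTB lower over the list alone, and adjusted p = 0.198 with an estimated correlation), with IL7R at 2713 ± 476 against 440.4 ± 168 CPM. Within type 1 genes IL18R1 and IL18RAP were higher and CCL5, IKZF3 and TBX21 lower over the list alone. LY9, a receptor of the SLAM family, was the single gene lower over all genes (2.16 ± 0.943 against 796 ± 784 CPM, edgeR adjusted p = 0.0262), and 15 were higher. LY9 lost its call without the low count filter and without donor 2, who gave no ILC2 sum. No gene was lower in either fit. Leaving out donor 3, 4 or 5 left 1 sum in lung or spleen ILC2, so those fits did not back the LY9 call either.

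The genes higher in lung ILC2 over all genes held surfactant and other lung epithelial genes. Lung epithelial markers summed to 44510 ± 59510 CPM in lung ILC2 and 18.8 ± 12.8 CPM in spleen ILC2, with 5 of 8 higher over all genes and 8 over the list alone (median 10.09, or 9.52 at the bounds, camera adjusted p = 5.34e-29, and 0.00257 with an estimated correlation). SFTPC, SLC34A2, PGC and FABP4 had no read in spleen ILC2 and were at least 22900-fold, 1497-fold, 2725-fold and 1266-fold higher, with counts pooled over both lung donors. SFTPC was at 729 and 30590 CPM in the 2 lung sums, and the lung epithelial list at 2426 and 86590 CPM. SFTPB stood at 8507 ± 11440 against 13.4 ± 10.1 CPM (edgeR adjusted p = 0.00108). SFTPA1, whose reads can be shared with its close copy SFTPA2, was higher too. Mast cell markers (105 ± 100.2 against 7.71 ± 5.96 CPM, 3 of 4 over the list alone, median 7.87, or 5.95 at the bounds, camera adjusted p = 9.23e-06) and stromal markers (615 ± 482 against 105 ± 41.6 CPM, 4.61, or 2.03 at the bounds, 8.58e-05) were higher. So were myeloid markers (10290 ± 2146 against 8894 ± 6584 CPM, 1.23, 3.48e-04), residency genes (1.12, 0.0462, with CD9 higher over the list alone) and NF-kB genes (0.35, 0.0128). These 5 lost the call with an estimated correlation (adjusted p = 0.0645, 0.363, 0.606, 0.458 and 0.592). B and plasma cell markers (235 ± 311 against 1739 ± 1498 CPM, 7 of 9 lower over the list alone, -6.48, 1.34e-09) and ribosomal protein genes (-0.95, 1.74e-08) were lower. Neither held with an estimated correlation (adjusted p = 0.123 and 0.592). Residency genes were not called without the 2 jejunum sums that stood apart (0.0738). The block called immediate early genes (0.028), interferon genes (0.0427), intestinal epithelial markers (0.00493) and erythroid markers (0.0191), at 0.702, 0.109, 0.112 and 0.137 without it. An estimated correlation ended these 4 calls (0.268 to 0.733). The block gave 28 higher and 1 lower genes, DESeq2 90, limma-trend 251, and the fit without the 2 apart sums 32. Leaving out each of the 5 donors in turn gave 16, 11, 5, 3 and 8 genes, of which 15, 10, 0, 3 and 7 were shared.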

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

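The tests of RNA from B and myeloid cells in spleen ILC2 were chosen after the result was seen, as were the fits without 2 jejunum sums that stood apart and without 3 jejunum NK sums rich in plasma cell RNA.

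Sums far from the others were sought in 145 sets of 4 or 5 donor sums. The sets covered key markers, marker lists of other cells and total counts (log2 scale), and the MTRNR2L percentage (unlogged). Of them 11 held such a sum, and chance picks out about 1 in 20 such groups, or 5%. In jejunum NK cells these were TBX21 (1.98 CPM, others 9.57 to 13.6), NCAM1 (168 CPM, others 86.7 to 91.5), the erythroid list (0 CPM, others 1.30 to 2.02) and the plasmacytoid dendritic list (84.2 CPM, others 3.81 to 7.43). In spleen NK cells they were KIT (0.447 CPM, others 5.27 to 6.57), NCAM1 (28.0 CPM, others 148 to 212) and PRF1 (1425 CPM, others 685 to 830.2). In spleen ILC3 they were EOMES (8.44 CPM, others 0 to 0.557), ITGA1 (1.53 CPM, others at 0) and the erythroid list (1560 CPM, others 0 to 0.543), and in jejunum ILC1 PTGDR2 (7.57 CPM, others at 0). No explanation was tested for them.

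Differences between tissue effects were tested as interactions. INSR (log2 difference -5.45, edgeR adjusted p = 0.0443) was higher in jejunum than in spleen NK cells (4.24) and not called in ILC1 (-1.21). KLHL6 (-3.41, edgeR adjusted p = 0.0434) was higher in jejunum NK cells (2.55) and not called in ILC3 (-0.86). For ILC1 against NK cells the lists that differed were heat shock (median -1.14, camera adjusted p = 6.03e-04), proliferation (1.04, 0.0258), ribosomal protein genes (-0.999, 9.8e-18) and B and plasma cell markers (-5.20, 1.25e-07). For ILC3 against NK cells they were KIR (-0.29, 0.0119, with the test pointing up while the median was negative), type 3 genes (-0.82, 0.022), heat shock (-0.57, 0.00128), proliferation (2.12, 3.59e-05) and ribosomal protein genes (-0.44, 0.0129). For ILC3 against ILC1 they were glycolysis (0.35, 0.00368), oxidative phosphorylation (0.51, 0.00131), ribosomal protein genes (0.57, 3.01e-10) and B and plasma cell markers (1.27, 0.00128). None of these 13 list calls held with an estimated correlation (adjusted p of 0.196 to 0.934). RLE scaling moved the median of all genes from 0.01 to 0.14 in the first interaction and from -0.06 to -0.23 in the last.

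Several of these interaction lists depended on single sums or on the donor term. Without the 2 jejunum sums that stood apart heat shock was not called (adjusted p = 0.0624 in the first and 0.604 in the second interaction), nor proliferation in the first (0.173). The same held for KIR and type 3 genes in the second (0.20 and 0.32), and for glycolysis, oxidative phosphorylation and ribosomal protein genes in the last (0.28, 0.919 and 0.0807). Without the 3 plasma-rich NK sums heat shock (0.962 and 0.879), proliferation (0.42, first), B and plasma cell markers (0.35, first) and ribosomal protein genes (0.861, second) were not called. With the donor as a block KIR and ribosomal protein genes were not called in the second interaction (0.0574 and 0.0527). The block called KIR (0.0213) and glycolysis (0.0467) in the first, B and plasma cell markers (0.00127) in the second, and heat shock (5.78e-04) and erythroid markers (0.0209) in the last, at 0.0554, 0.0903, 0.191, 0.928 and 0.129 without it. None of these 5 held with the block and an estimated correlation (0.268 to 0.664).

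In the libraries labelled lung ILC3, which entered no comparison, marker lists of other cells lay above the highest spleen sum of any group. Myeloid markers were at 15680 CPM (spleen up to 13550), mast cell at 182 CPM (up to 11.9) and intestinal epithelium at 1243 CPM (up to 118). Lung epithelium was at 40020 CPM (up to 43.3), stroma and endothelium at 251 CPM (up to 134) and plasmacytoid dendritic at 154 CPM (up to 58.3). The lung ILC2 sum of the same donor was higher in lung epithelium (86590 CPM), intestinal epithelium (2428 CPM) and stroma and endothelium (274 CPM). It was lower in mast cell (176 CPM), myeloid (8775 CPM) and plasmacytoid dendritic markers (102.5 CPM).

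The 20 genes higher in jejunum NK than in spleen NK cells had a median log2 fold change of 4.34 while jejunum NK sums held RNA of plasma cells and epithelium. Without the 3 sums rich in plasma cell RNA the median was 3.92 (lower quartile 1.67, 19 of 20 positive), and without the 3 sums with the most epithelial RNA it was 4.30 (lower quartile 2.82, 20 of 20 positive). The 20 genes were called in a fit that held the kept sums, which favors genes high in those sums. Without the plasma-rich sums, the kept jejunum NK sum of donor 2 still held 1935 CPM of B and plasma cell markers. Neither median therefore decides about either source. Of the 24 genes called between the tissues, 6 were called again without the plasma-rich sums. Single genes such as DERL3 may still owe their level to plasma cells. RNA of either source or of both, another cell type, and a difference between the tissues or their digestion stay open.

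Helper ILC genes were lower in spleen ILC2 than in spleen ILC1, where B cell and myeloid RNA was high in ILC2. In spleen ILC1 of the same 2 donors, at a mean of 1846 CPM of the B and plasma cell list against 1739 CPM in ILC2, the genes were higher by a median log2 ratio of 1.43 (lower quartile 0.89). That ratio repeats the pattern in the same ILC2 sums, and the B cell level was equal only as a mean (2039 against 2798 and 1652 against 680 CPM), so it decides nothing about B cells. In lung ILC2, at 10290 CPM of the myeloid list against 8894 CPM, they were higher by 2.03 (lower quartile 1.81). This last value rests on the same spleen ILC2 sums and sets them against another tissue. The myeloid level was equal only as a mean (8775 and 11810 against 4239 and 13550 CPM), so it decides nothing about myeloid cells. B cells, myeloid cells, a mixture of both, other cells and a biological difference of ILC2 stay open.

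Other splits of the same sums into groups of the same sizes were fitted as a test of chance. At most 60 splits were fitted per test, the real one included. Where more were possible (126 for groups of 5 and 5 or 4 and 5 sums) the others were a random draw. As many genes as in the real split were called by under 5% of the fitted splits in 4 comparisons. Spleen ILC1 against NK had 8 genes (highest other split 2, 1 of 60 splits). Spleen ILC3 against NK had 507 (highest other 5, 1 of 60). Spleen ILC3 against ILC1 had 21 (highest other 22, 2 of 60), and jejunum against spleen NK 24 (highest other 21, 1 of 60). The share was 5% or more for jejunum ILC3 against NK (86, highest other 93, 3 of 56), jejunum ILC3 against ILC1 (2, highest other 2077, 8 of 35), and the first and the second interaction (1 each, highest others 116 and 265, 5 of 60 each). Where the real value was 0 every split was as large by construction, so nothing about chance was tested: jejunum ILC1 against NK (highest other 656, 60 of 60), jejunum against spleen ILC1 (1035, 60 of 60), jejunum against spleen ILC3 (1, 56 of 56) and the third interaction (243, 60 of 60). The groups shared donors, and the real split parted the sums of every shared donor, while most others kept both sums of a donor together. Only 10, 8, 8 and 7 of the fitted splits, the real one included, parted as many pairs in the first 4 comparisons. Their highest other values were 0, 0, 2 and 0. In jejunum ILC3 against NK there were 8 (highest other 0), in jejunum ILC3 against ILC1 12 (23), and in the first 2 interactions 6 and 2 (0 in each). These are too few for a share under 5%. The highest other values of such splits were 7, 558 and 1 in the 3 jejunum comparisons at 0, and 0 in the third interaction. Splits that called several times the real count (656, 1035, 2077, 116, 265 and 243) point to a structure of the samples: those with 656, 1035 and 2077 genes grouped the jejunum ILC1 sum that stood apart with 2 or 3 others, and the one with 2077 held the jejunum ILC3 sum that stood apart as well. The split with 93 genes set that ILC3 sum and 2 NK sums against the rest.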

How the results depend on the processing

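The fits without 2 jejunum sums that stood apart and without 3 jejunum NK sums rich in plasma cell RNA were chosen after the data were seen, and the other alternatives in advance. Results are given in a fixed order. It starts with spleen ILC1 against NK (8 genes), spleen ILC3 against NK (507) and spleen ILC3 against ILC1 (21). Next come jejunum ILC1 against NK (0), jejunum ILC3 against NK (86), and jejunum ILC3 against ILC1 (2), then jejunum against spleen NK (24), ILC1 (0) and ILC3 (0). Last are spleen ILC2 against ILC3 (0) and ILC1 (1), lung against spleen ILC2 (16), and the interactions ILC1 with NK (1), ILC3 with NK (1) and ILC3 with ILC1 (0). A count that moved by over 1.5 times is given, and the cause was not tested unless stated.

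DESeq2 moved all 15 counts, to 130, 889, 155, 1032, 333, 269, 280, 1203, 55, 403, 159, 90, 25, 34 and 15. RLE scaling moved 6: spleen ILC1 against NK to 3, jejunum ILC1 against NK to 823, and jejunum against spleen ILC1 to 723. It also moved spleen ILC2 against ILC3 to 8 and ILC1 to 2, and the ILC1 with NK interaction to 0. Testing genes without a low count filter moved 4: jejunum ILC1 against NK to 4, spleen ILC2 against ILC3 to 1 and ILC1 to 2, and the ILC3 with NK interaction to 0. limma-trend with equal weights of libraries moved 11: spleen ILC1 against NK to 39, spleen ILC3 against ILC1 to 127, jejunum ILC3 against ILC1 to 5, and jejunum against spleen NK to 71, ILC1 to 9 and ILC3 to 1. The rest were spleen ILC2 against ILC3 to 453 and ILC1 to 209, lung against spleen ILC2 to 251, and the first 2 interactions to 0 each. No library lay under 0.1 of the median total, so leaving such libraries out changed nothing.

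The donor as a block moved 12 counts: spleen ILC1 against NK to 48, spleen ILC3 against ILC1 to 65, jejunum ILC1 against NK to 2, ILC3 against NK to 140 and ILC3 against ILC1 to 8. Further ones were jejunum against spleen NK to 95, ILC1 to 10 and ILC3 to 3, spleen ILC2 against ILC3 to 46 and ILC1 to 9, lung against spleen ILC2 to 29 and the ILC1 with NK interaction to 7. Of 140 list calls 136 held with the block, and beyond the calls given beside their results the block changed no other call. All 96 calls of genes named by rank held with the block, where a gene named in several comparisons counts once in each.

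Without the 2 jejunum sums that stood apart 9 counts moved: spleen ILC1 against NK to 14, spleen ILC3 against ILC1 to 38, jejunum ILC1 against NK to 1, and jejunum against spleen NK to 144. Others were spleen ILC2 against ILC3 to 203 and ILC1 to 11, lung against spleen ILC2 to 32, and the first 2 interactions to 3 and 0. Without the 3 jejunum NK sums 6 moved: spleen ILC1 against NK to 19, jejunum ILC3 against NK to 30, spleen ILC2 against ILC3 to 12 and ILC1 to 2, and the first 2 interactions to 0 each. Counts of comparisons without those sums moved because all groups share the filter, the scaling and the estimate of dispersion.

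Leaving out each of the 5 donors in turn gave, in the order above, 0 to 7, 303 to 346, 0 to 26, 0 to 2, 7 to 91, 0 to 2, 0 to 15, 0 to 0, 0 to 0, 0 to 167, 0 to 3, 3 to 16, 0 to 1, 0 to 1 and 0 to 0 genes. It also leaves fewer samples, and a group left with 1 donor was assumed to vary like the others.

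Of the 140 list calls 28 held with an estimated correlation and 112 were lost, and with the block and an estimated correlation 42 held, with none gained. Without the 2 sums that stood apart 115 held, without the 3 NK sums 120, and leaving out a donor gave 130 to 152 calls. Of the 96 calls of genes named by rank 94 held with DESeq2, 90 with RLE scaling, 92 without a filter and 87 with limma-trend. The number was 94 without the 2 sums that stood apart, 70 without the 3 NK sums, and 46 to 68 when a donor was left out. None of them changed direction in these fits. Agreement of libraries over genes of at least 10 CPM was lower, with a median rho of 0.813 for repeat libraries (0.849 over all tested genes). Simulated changes of 4-fold were recovered at 44% in spleen ILC3 against NK and at 2% in lung against spleen ILC2, so small changes with 2 donors were beyond this depth and number of donors.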

Other observations

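Lung NK cells and lung ILC3 came from 1 donor each and were read as single values. The lung NK library (1 donor) had the profile of killer cells, with PRF1 at 2098 CPM, GNLY at 1507 CPM, KLRD1 at 1612 CPM and S1PR5 at 422 CPM, the last beside 311 ± 145 CPM in spleen NK and 21.1 ± 25.4 CPM in jejunum NK cells. Its EOMES stood at 59.9 CPM, TBX21 at 19.7 CPM, IL7R at 42.8 CPM and KIT at 9.41 CPM, and CD69, an early activation and residency gene, at 696 CPM. The lung ILC3 sum (1 donor, 2 libraries) had IL7R at 1058 CPM with KIT at 35.7 CPM and IL23R at 5.94 CPM, beside 753 ± 321 and 102 ± 16.5 CPM in spleen ILC3. Of the type 2 list, IL1RL1 was at 46.1 CPM, HPGDS at 18.3 CPM, IL17RB at 13.4 CPM and GATA3 at 2.97 CPM. Mast cells express the first 2 as well, and mast cell markers summed to 182 CPM in it (TPSAB1 at 82.7 CPM) and myeloid markers to 15680 CPM. SFTPC, a surfactant gene of alveolar cells, was at 13220 CPM.

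Some lists were called in no comparison or interaction without the donor block. Gut homing genes came nearest in jejunum ILC3 against NK (median -2.04, camera adjusted p = 0.0728, and 0.0834 with the donor as a block), and CCR9, a receptor for a chemokine of small intestine, was higher over the list alone in jejunum than in spleen NK cells (156 ± 123 against 15.6 ± 10.7 CPM, list median 1.17, 0.173) and ILC1 (121 ± 83.9 against 9.77 ± 7.40 CPM, list median 0.05, 0.941). TGF-beta response genes came nearest in jejunum ILC3 against ILC1 (0.45, 0.312), and interferon stimulated genes in spleen ILC2 against ILC1 (0.51, 0.0626). Erythroid markers came nearest in the ILC3 with ILC1 interaction (camera adjusted p = 0.129).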
